A study of Mus musculus with 2 samples.

How the data were processed

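Single-cell RNA was measured in 2 libraries labelled as T cells from an Nras-mutated mouse melanoma model on day 5, 1 untreated and 1 treated with trametinib plus BGB-283. The libraries were made with a droplet 3' kit, per the labels. Reads were processed with Cell Ranger and Seurat, with no version given, per the submitters' processing notes. The same notes name the human build GRCh38 although the symbols are mouse symbols, so no coordinates are given. The authors deposited 1 table of 15121 genes and 17390 cells as the natural log of 1 plus the UMIs per 10000 UMIs of each cell. The back-transformed values of every cell summed to 10000, and after scaling by the smallest value of each cell, 38204229 of 38204229 nonzero values were whole within 0.01 (100.0%). UMIs were recovered in this way and used for all main values. The design had planned means on the deposited scale for values that were not counts, so this is a departure from it, and the differences of mean deposited values were added as an alternative.

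The deposited cells had at least 503 and 501 genes and at most 19.8% and 20.0% mitochondrial UMIs. No UMI was present for 13 genes. The table appears filtered by library before deposit, since 492 genes had no UMI in the untreated and 644 in the treated library while 25 and 27 genes were seen in only 1 cell. A gene at 0 over a whole library was therefore treated as not measured there, a choice made after the values were seen, and 13998 genes had UMIs in both. Ratios, gene lists and V segment shares used those genes.

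Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 216 untreated and 358 treated cells. The automatic Scrublet threshold marked 0.033% and 0.013% of cells and was taken as not working. Cells scoring above the cut for the highest 5% of each library were therefore removed (426 and 377, or 4.68% and 4.88%). The libraries were clustered together by the Leiden method at resolution 1.0 on 30 principal components of 2000 variable genes with 15 neighbours, without batch correction and without receptor segment, mitochondrial, ribosomal and sex-linked genes. Of the 2000 variable genes, 176 were at 0 in a whole library. Clusters were named from marker genes fixed beforehand, while the thresholds of the naming rule were written after a first clustering and revised once. Naive and cycling markers were read as states that any T cell class can have, and a stricter reading that leaves out clusters led by them was added as an alternative. Clusters 16 and 14 were kept out of the CD8 and CD4 classes by the rule. Class names come from this clustering, and no annotation by the authors was used.

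UMIs were summed per library and class and given as CPM of the class total. Exact Poisson intervals, exact conditional binomial intervals for ratios and Clopper-Pearson intervals for shares were computed at the 95% level. With 1 library per group no test, p-value or standard error was computed. Genes were named by a rule fixed beforehand. It took genes with at least 50 UMIs and 20 CPM in 1 of the libraries, ranked by the interval bound nearest 1, and named the 12 highest and 12 lowest in all T-like cells and the 8 highest and 8 lowest in each T cell class. It added the 2 highest and 2 lowest members of each gene list in all T-like and CD8 T-like cells, and 18 genes always. Some genes that the rule names are not reported here. Segment, ribosomal, mitochondrial, predicted and sex-linked genes were not eligible. Named outside the rule after their values were seen were Dusp4, Dusp5, Phlda1 and Spred2 in all T-like cells, and Aldoa and Slc2a1 in regulatory T-like cells. Of 20 gene lists fixed beforehand, 19 gave medians over members at 20 CPM or more, each set against 10000 random lists of the same size matched in 10 expression bins, with 1000 Poisson redraws for its interval. The list of sex-linked genes served as a check of the labels: Xist was at 877 and 1075 CPM in all T-like cells and Ddx3y had 1 UMI in each library. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs.

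The gene ratio step was tested on simulated Poisson counts with 200 changed genes. These held no variation between cells or libraries beyond counting error, which the intervals assume as well. The test therefore checks the calculation and does not show how far the real ratios can be relied on. In all T-like cells and CD8 T-like cells (5526 and 5514 genes) the interval excluded 1 in the simulated direction for 100.0% of genes changed 1.5-fold. In CD4 helper T-like cells (5270 genes) this held for 73.1% of genes changed 1.5-fold and 95.5% of genes changed 2.0-fold, and in regulatory T-like cells (5560 genes) for 98.5% of genes changed 1.5-fold. Alternatives covered the cell filter, doublet removal, resolution, components, class definition, denominator, scaling, expression minimum, cycling clusters and thinning. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.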

Results

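The data are single-cell transcriptomes of cells labelled as T cells from a syngeneic mouse melanoma model, NILER in the labels, that was derived from the Nras-mutated line NIL and exposed to ultraviolet light to raise its mutation load. The series concerns resistance to MEK inhibitors and T cell immunity, and the comparison asked how the T cell compartment differed under combined treatment. Material was taken on day 5 from an untreated group and from a group given trametinib, an inhibitor of the kinases MEK1/2, together with BGB-283, a RAF inhibitor. Each group was represented by 1 droplet library, so no spread between animals or libraries could be estimated, no test was possible, and treatment and batch could not be told apart. The untreated library held 9312 cells and 95349992 UMIs, with a median of 6155 UMIs and 1804 genes per cell. The treated library held 8078 cells and 58318786 UMIs, with a median of 5987.5 UMIs and 2047 genes per cell. After filtering, 8670 untreated and 7343 treated cells entered the comparisons. Intervals are exact 95% intervals and cover counting error only. Genes are given by the mouse symbols of the deposited table, and levels are UMIs scaled to the total of the cell class named (CPM).

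The first comparison asked which cells the 2 libraries held. Cells with CD8 T cell markers made up 44.2% of untreated cells (43.2 to 45.3) and 65.3% of treated cells (64.2 to 66.4). CD4 helper T-like cells made up 15.1% (14.4 to 15.9) and 4.41% (3.95 to 4.91). Foxp3-expressing regulatory T-like cells made up 9.02% (8.42 to 9.64) and 8.17% (7.55 to 8.82), and other T-like clusters 14.04% and 9.82%. Dendritic-like cells made up 6.29% of the untreated and 1.85% of the treated library, clusters with both T cell and macrophage transcripts 8.005% and 2.32%, and macrophage or monocyte-like cells 0.311% and 2.59%. Together the T-like clusters made up 82.4% (81.6 to 83.2) and 87.7% (86.9 to 88.5). The labels do not describe the sort, which can set all of these shares.

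Most clusters came from 1 library. Of 38 clusters, 24 drew at least 90% of their cells from 1 library, and these held 79.8% of all cells. The CD8 T-like class lay mainly in clusters 1, 2, 9, 13 and 18 in the untreated library and in clusters 0, 3, 5, 8 and 17 in the treated library. CD4 helper T-like cells lay in clusters 4 and 12 against cluster 19, and regulatory T-like cells in clusters 6 and 26 against mainly cluster 11, with 88 treated cells in cluster 6. Cluster 16, led by Gzmf, Gzme, Gzmd and Gzmg, granzyme genes of killer cells, was kept out of the CD8 class by the naming rule and held 4.54% of untreated and 0.0681% of treated cells. Cd8a and Cd8b1 were each found in 99.2% of its cells and Cd4 in 3.76%. Cluster 14, led by Il1rl1 and Hdc, was kept out of the CD4 class and held 2.71% and 2.49%. Cells were also named by their own UMIs, over all cells that passed the filters. A UMI of Cd3e, Cd3d, Cd3g or Trac made a T cell, and UMIs of Foxp3, Cd8a, Cd8b1 and Cd4 set its class. Cells outside the T-like clusters could therefore enter, such as those of cluster 7, with both T cell and macrophage transcripts. Cluster 7 held 694 untreated and 5 treated cells, with Cd4 in 40.8% and Foxp3 in 13.2% of them. This naming gave 53.05% and 67.4% CD8 T cells, 11.4% and 6.80% CD4 helper T cells, and 92.3% and 92.6% T cells. Without the clusters led by naive or cycling genes, CD8 T-like cells made up 9.35% and 62.7%, and CD4 helper T-like cells 4.76% and 4.36%. For CD8 this left out clusters 1, 2, 13 and 34, with mostly untreated cells, and for CD4 cluster 4. Clusters 5 (805 treated cells) and 18 (283 untreated cells), with naive-state markers, stayed in, and cluster 16 stayed out. The CD8 shares in this setting therefore do not compare only cells outside the naive state.

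**Figure D1:**
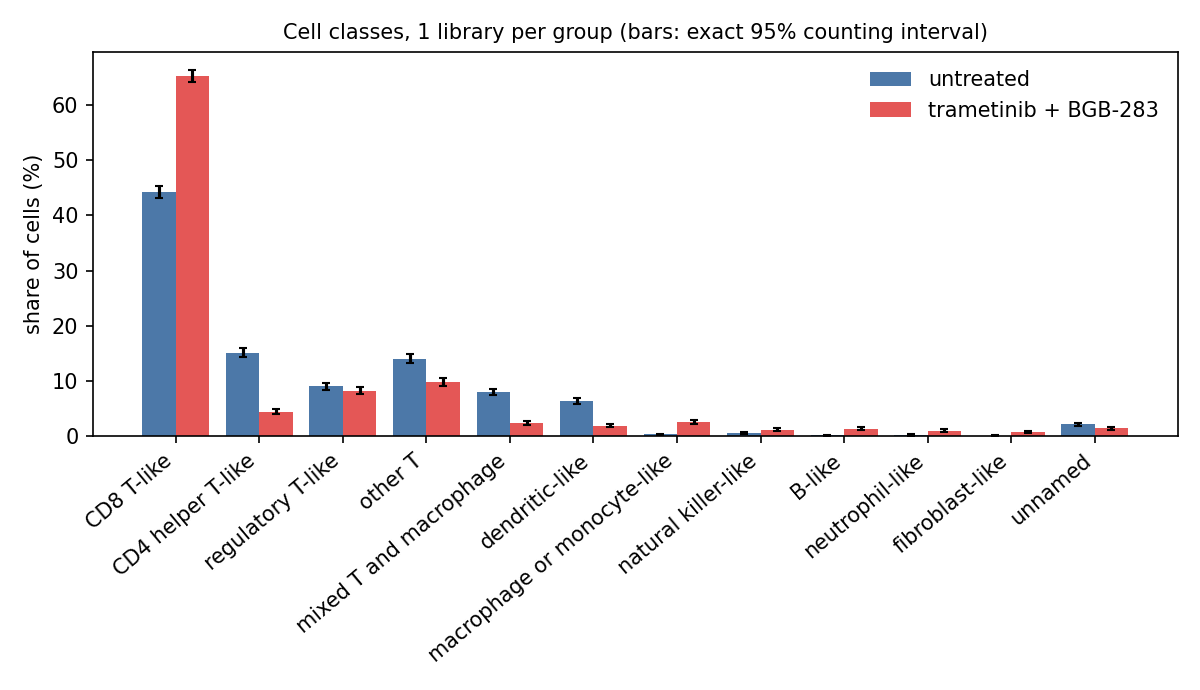
Share of cells (percent, vertical axis) in each cell class (horizontal axis) of the untreated and the treated library, with exact 95% counting intervals as error bars. CD8 T-like cells made up 44.2% and 65.3%, and CD4 helper T-like cells 15.1% and 4.41%.

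In all T-like cells, genes switched on by T cell receptor signalling went both ways between the libraries. Nr4a3, an orphan nuclear receptor induced by antigen receptor signals, was at 44.7 CPM in the untreated and 566 CPM in the treated library, 12.7-fold higher (12.1 to 13.2). Fosl2, an AP-1 transcription factor, was at 102 and 674 CPM, 6.62-fold higher (6.43 to 6.82). The AP-1 gene Jun was at 197 and 92.4 CPM, 2.13-fold lower (2.06 to 2.21), and Fos at 160 and 96.6 CPM, 1.66-fold lower (1.60 to 1.72). Jun and Fos also belong to the list of heat shock and dissociation stress genes, so their lower levels may not reflect receptor signalling. Klf2, a factor that maintains T cell quiescence and recirculation, was at 702 and 90.8 CPM, 7.73-fold lower (7.48 to 7.99). The granzyme gene Gzmc was 8.97-fold lower (8.47 to 9.51) and the pore-forming protein gene Prf1 3.16-fold lower (3.04 to 3.29). As the mean of the CPM of each cell, their log2 ratios were -2.27 against -3.17 for Gzmc and -0.96 against -1.66 for Prf1, and Gzmc had -2.41 with cells named by their own UMIs. The highest ratios of all belonged to Zc3hav1l, at 2.06 and 62.1 CPM, and Osgin1, a stress response gene, at 4.42 and 71.9 CPM. Irs2, an insulin receptor substrate, was 10.2-fold higher, Hexim1, an inhibitor of transcription elongation, 6.76-fold, and the lipid desaturase gene Scd2 6.72-fold. Rhoq, Rab43, Cpeb2 and Fbxl22 were between 7.57-fold and 8.18-fold higher. The hemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 had the lowest ratios, with Hbb-bs at 153 and 1.20 CPM, and Dapl1, Gzmg, Igfbp4, Tespa1 and Pdlim4 were also among the 12 lowest. With cells named by their own UMIs, Igfbp4 had a log2 ratio of -0.65 against -3.10 by clusters, and Gzmg -2.00 against -3.54. The class II MHC genes H2-Aa, at 57.3 and 9.63 CPM, and H2-Eb1, at 59.8 and 10.2 CPM, were lower as well, beside the lower share of dendritic-like cells, which express both.

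By gene list, the naive and memory genes had a median log2 ratio of -1.35 in all T-like cells, with 11 of 15 members at least 1.5-fold lower and 0 higher, below all of 10000 random lists matched on expression. Tcf7 was at 171 and 71.4 CPM and Ccr7 at 276 and 104 CPM, while Satb1 and Bach2 were within 1.5-fold. The ERK pathway output list had a median of 1.28, at the 99.95th percentile, with 6 of its 8 measured members higher and 1 lower. With no minimum beyond 10 UMIs, 15 of its 16 members entered and the median was 0.67. Egr1 was 6.17-fold higher, the feedback inhibitor gene Spry2 3.33-fold (3.09 to 3.59), and Dusp5, Phlda1, Dusp4 and Spred2 were the other 4. Myc, an ERK target as well, was at 31.0 and 7.43 CPM, 4.17-fold lower (3.70 to 4.71). The phosphatase gene Dusp6 stayed below the 20 CPM minimum, at 15.01 and 15.03 CPM. Egr1 and Myc also belong to other lists named here. When T cells were named by their own UMIs, the ERK list had a median of 0.81, Egr1 a log2 ratio of 0.88 and the immediate early gene Ier3 -1.36, against 0.19 by clusters.

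Cell cycle and type I interferon genes were mostly lower. The G2M list had a median of -1.14 in all T-like cells with 12 of 13 members lower, among them Ccnb1 at 26.2 and 7.23 CPM, and the S phase list -0.74 with 8 of 13 lower. Pcna, a replication and repair factor, was at 87.2 and 185 CPM. The type I interferon list had a median of -0.89 with 8 of 11 lower, including Ifit3, 4.32-fold lower (3.93 to 4.76), and Usp18, 3.99-fold. Among 14 cytotoxic genes the median was -0.70, with 7 lower and 2 higher, Gzmb at 624 and 307 CPM against Gzmk at 20.9 and 50.4 CPM and the death ligand gene Fasl at 29.2 and 91.2 CPM. As differences of mean deposited values, the cytotoxic median was 0.104 and Gzmb 0.142 natural log units, both higher in the treated library, so no order is given for this list or gene. Inhibitory receptor and exhaustion genes, called the inhibitory receptor list here, had a median of 0.46, with 4 of 11 at least 1.5-fold higher and 0 lower. The list also holds genes that do not encode receptors on the cell surface. Among the 4 were 2 of these, Nr4a2, at 158 and 935 CPM, and Tox, a factor of chronic stimulation, at 76.0 and 193 CPM. Nr4a2 is also in the immediate early list. Less than 1.5-fold apart were Pdcd1, which encodes PD-1, at 208 and 286 CPM, Lag3 at 138 and 191 CPM and Havcr2 at 33.4 and 43.5 CPM.

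Among the other lists in all T-like cells, immediate early genes had a median of 0.57, with 6 of 13 higher and 2 lower, cell death and p53 genes 0.40, tissue residency genes 0.43, regulatory T program genes 0.38, glycolysis genes -0.58 and chemokine genes -0.75. The medians of the inhibitory receptor (93.2nd percentile), cell death (85.1), tissue residency (88.4) and regulatory T program lists (89.9) lay inside the 95% range of the matched random lists. The chemokine median was 0.0143 natural log units as a difference of mean deposited values. The tissue residency median came to -0.00 when ribosomal and mitochondrial genes were left out of the total, and the regulatory T program median to -0.03 with a minimum of 100 CPM. Ribosomal protein genes had a median of -0.38 with 0 of 16 members beyond 1.5-fold, mitochondrial transcripts -0.19, heat shock and dissociation stress genes -0.14, and oxidative phosphorylation genes -0.07. Activation genes had a median of 0.05 and interferon gamma and MHC class I genes 0.05, the latter with 2 of 14 higher and 3 lower, and both turned negative under other scalings, while the heat shock median turned positive. Within the stress list, Hspa1a was at 206 and 58.0 CPM, against Dnaja1 at 389 and 1014 CPM. Il2ra was 2.16-fold higher, Cd8a 1.24-fold, and Foxp3 and Cd4 had counting intervals that covered 1.

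**Figure D2:**
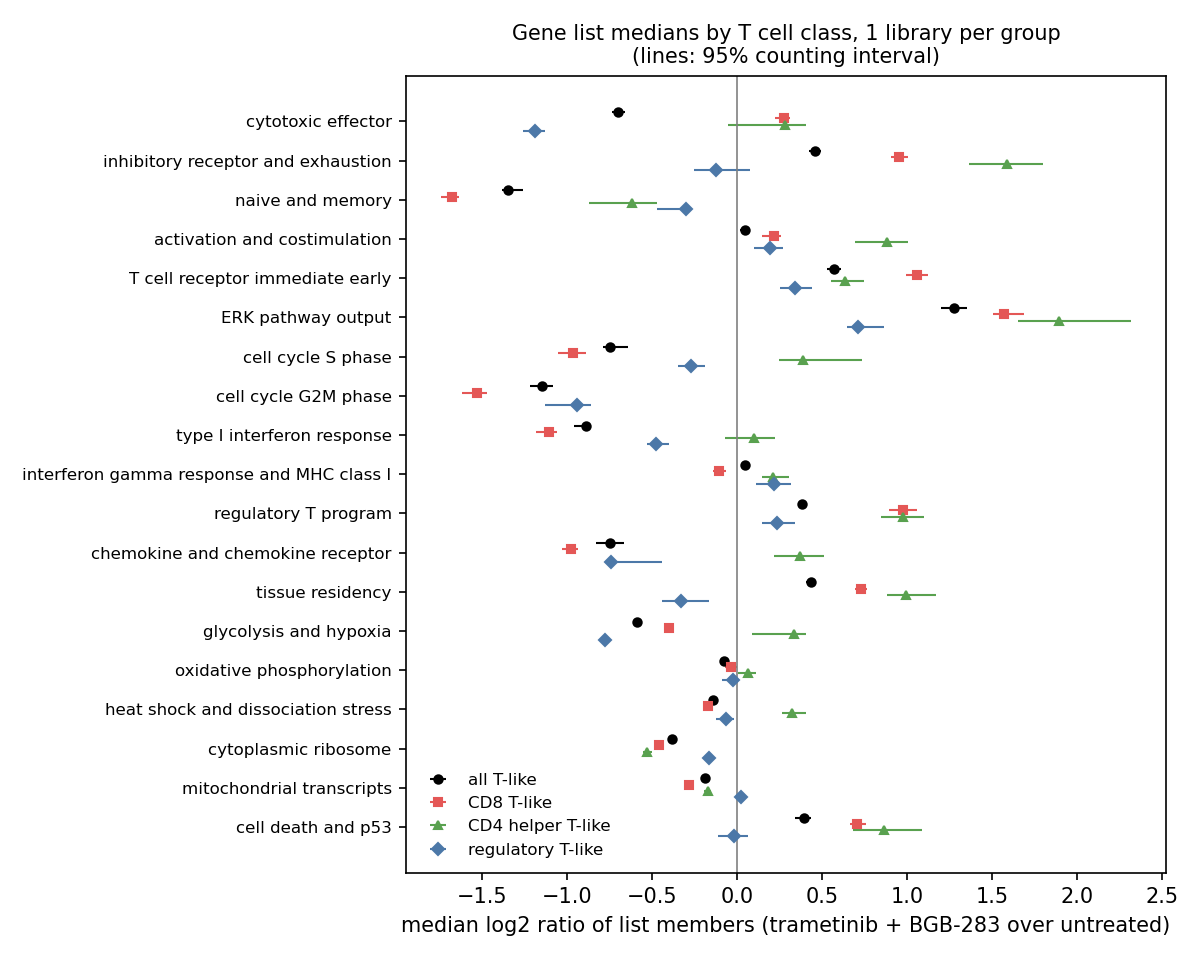
Median log2 ratio of the measured members of each gene list, treated over untreated (horizontal axis), in 4 T cell classes, with 95% counting intervals as lines. The naive and memory list lies at -1.35 in all T-like cells and at -1.67 in CD8 T-like cells, and the ERK pathway output list at 1.28 and 1.57.

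In CD8 T-like cells (3833 untreated and 4796 treated cells, with 30632637 and 33242837 UMIs), Nr4a3 was at 30.1 and 587 CPM, 19.5-fold higher (18.3 to 20.9). Crem, a regulator of cyclic AMP responses, was at 67.8 and 952 CPM, Nr4a2 at 116 and 1063 CPM, and Fosl2 at 66.5 and 713 CPM. Fos was at 162 and 68.6 CPM, 2.36-fold lower (2.25 to 2.49), and Jun at 205 and 92.4 CPM, 2.22-fold lower (2.13 to 2.32). Naive genes were lower, with 13 of 15 list members at least 1.5-fold lower and a median of -1.67: Klf2 was at 829 and 81.8 CPM, Ccr7 at 254 and 79.7 CPM, and Tcf7, a factor of naive and stem-like T cells, at 191 and 49.1 CPM. The inhibitory receptor list had a median of 0.95, with 9 of 11 higher, including Tox at 64.4 and 226 CPM, 3.50-fold higher (3.33 to 3.68), Pdcd1 at 174 and 337 CPM, Lag3 at 143 and 239 CPM, and Havcr2 at 28.6 and 50.7 CPM. The adhesion receptor gene Cd44 was 4.05-fold higher and the costimulator gene Icos 4.12-fold, while Cd69, an early activation marker, was at 205 and 64.6 CPM. The ERK list had a median of 1.57, or 0.97 with no minimum beyond 10 UMIs, with Egr1 6.91-fold, Phlda1 4.63-fold and Spry2 4.48-fold higher, and Myc 6.24-fold lower (5.39 to 7.25). Type I interferon genes had a median of -1.10, with Usp18 at 42.5 and 6.89 CPM and Ifit3 at 62.6 and 10.8 CPM. Cluster 18 of this class, led by Ifit3, held 283 untreated and 34 treated cells. Without the clusters led by naive or cycling genes, which leaves cluster 18 in, the median was -2.35, with log2 ratios of -4.16 against -2.63 for Usp18 and -4.27 against -2.54 for Ifit3.

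The composition of this class differed, since 78.8% of its untreated and 18.9% of its treated cells lay in clusters with naive-state markers. Leaving out the clusters led by naive or cycling genes kept mainly clusters 9 and 18 of the untreated library and clusters 0, 3, 5, 8 and 17 of the treated library, so clusters 18 and 5, with naive-state markers, stayed in. The naive list then had a median of -0.71, the ERK list 1.04 and the inhibitory receptor list 0.20. In that comparison Nr4a3 had a log2 ratio of 4.23, Crem 3.71, Fosl2 3.82, Egr1 2.86, Tox 1.49, Klf2 -2.10 and Tcf7 -0.83. Pdcd1 (-0.04), Lag3 (-0.63) and Havcr2 (-0.17) were no longer higher, and Ifng, the interferon gamma gene, changed sign from 0.40 to -1.23. Lag3, Ifng and Prf1 are among the top genes of cluster 9 (489 untreated cells), the main untreated cluster left. Their ratios in that comparison therefore depend on this reference. Among cells named by their own Cd8a or Cd8b1 UMIs, Nr4a3 had a log2 ratio of 3.82, Tox 1.71, Pdcd1 0.71, Lag3 0.59, Havcr2 0.32, Klf2 -3.10 and Tcf7 -1.71. Trdc, a gamma delta receptor gene, was at 24.1 and 2.497 CPM in the class.

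Cytotoxic genes went both ways in CD8 T-like cells. Prf1 was at 213 and 89.3 CPM, 2.39-fold lower (2.28 to 2.49), Gzmc at 248 and 29.2 CPM and Gzma at 74.6 and 23.0 CPM. Gzmc had a log2 ratio of -3.09, but -0.73 without the cycling clusters and -1.74 as the mean of the CPM of each cell. Prf1 had -1.25, but -0.72 and -0.62 in the same settings and -2.11 without the clusters led by naive or cycling genes. Gzma had -0.94 without the cycling clusters, against -1.70. Gzmb was at 632 and 345 CPM, a log2 ratio of -0.87, but -0.01 without the cycling clusters and higher by 0.341 natural log units as mean deposited values, so no order is given for it. Fasl was at 26.8 and 112 CPM, 4.18-fold higher (3.88 to 4.52), and Gzmk, a granzyme of memory-like and pre-exhausted cells, at 22.1 and 65.0 CPM. Without the clusters led by naive or cycling genes, Fasl had a log2 ratio of 1.17 against 2.07, and Gzmk 0.51 against 1.56. The list median was 0.28, but -0.73 with the granzyme-led cluster 16 added back, -0.79 with cells named by their own UMIs, -0.58 under the stricter cell filter and -0.13 without the clusters led by naive or cycling genes. The chemokine list had a median of -0.98, with Xcl1 at 112 and 16.5 CPM and Ccl5 at 1422 and 3184 CPM, and turned to 0.56 when genes unmeasured in 1 library were left out of the clustering. Ccl1 was 21.5-fold lower, and Osgin1, Zc3hav1l, Irs2, Ell2 and Rhoq were between 13.5-fold and 37.1-fold higher.

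Other lists in CD8 T-like cells had medians of -1.53 for G2M genes, with 14 of 14 lower, -0.96 for S phase, 1.06 for immediate early genes, with 8 of 13 higher and 2 lower, 0.98 for regulatory T program genes and 0.73 for tissue residency genes, among which Itga1 was at 3.75 and 30.8 CPM and Litaf at 68.3 and 377 CPM. Without the clusters led by naive or cycling genes the tissue residency median was 0.06 and the regulatory T program median 0.40, and the latter was 0.20 with no minimum beyond 10 UMIs. Cell death and p53 genes had a median of 0.71, with Cdkn1a at 33.6 and 94.9 CPM and Bcl2 at 271 and 86.8 CPM. Cdkn1a had a log2 ratio of 1.498, but 0.53 with cells named by their own UMIs and 3.355 without the cycling clusters. Ribosomal protein genes stood at -0.46, glycolysis genes at -0.40, mitochondrial transcripts at -0.28, heat shock genes at -0.17, interferon gamma and MHC class I genes at -0.10, oxidative phosphorylation genes at -0.03 and activation genes at 0.22. Of these, the glycolysis, heat shock, interferon gamma, oxidative phosphorylation and activation medians changed sign under at least 1 alternative. The cytotoxic, tissue residency, cell death, mitochondrial, heat shock, interferon gamma, oxidative phosphorylation and activation medians lay inside the 95% range of the random lists. Over the 9703 genes of this class with at least 50 UMIs in both libraries the median log2 ratio was 0.12. Scaling by the median of ratios moved the naive list to -1.79 and the ERK list to 1.45.

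**Figure D3:**
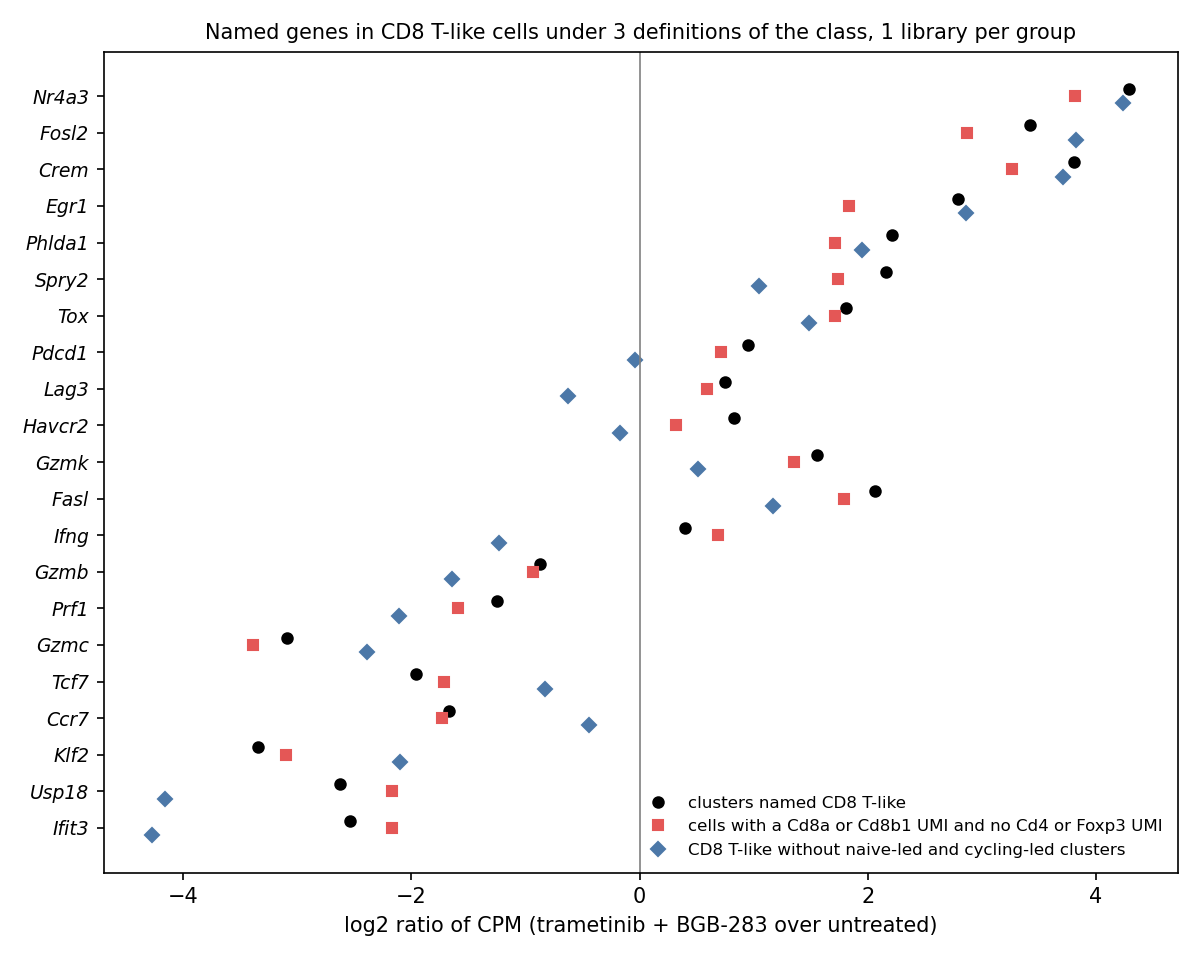
Log2 ratio of CPM, treated over untreated (horizontal axis), for named genes in CD8 T-like cells, with points for the clusters named CD8 T-like, for cells called by their own UMIs, and for the clusters not led by naive or cycling genes. Nr4a3, Fosl2, Crem and Egr1 lie above 0 and Klf2 and Prf1 below 0 in all 3, while Pdcd1, Lag3, Havcr2 and Ifng fall on both sides.

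Shares of CD8 T-like cells with at least 1 UMI were compared after thinning every cell to 2000 UMIs, which left out 101 untreated and 97 treated cells. Tox was detected in 8.68% of untreated (7.80 to 9.63) and 32.1% of treated cells (30.8 to 33.5), Pdcd1 in 11.5% and 39.5%, and Lag3 in 10.3% and 30.9%. Gzmb was detected in 17.9% and 32.1%, the opposite order to its CPM. Tcf7 was detected in 36.7% and 9.49%, and Ccr7 in 37.1% and 10.9%. Among 184 thinned macrophage or monocyte-like cells of the treated library, Tox was found in 4.35%, Pdcd1 in 3.26%, Lag3 in 4.35%, Gzmb in 3.26%, Tcf7 in 1.63% and Ccr7 in 1.09%. Among 26 such cells of the untreated library, Tox, Pdcd1 and Lag3 were found in 0 (0 to 13.2%), a bound above their untreated shares in CD8 T-like cells, Gzmb in 1, Tcf7 in 4 (15.4%, 4.36 to 34.9) and Ccr7 in 3 (11.5%, 2.45 to 30.2). Median depths before thinning were 6008 and 6325 UMIs in the CD8 T-like cells and 9385 and 8962.5 UMIs in the macrophage or monocyte-like cells. Unthinned shares were 24.8% and 56.8% for Tox, 19.8% and 64.5% for Pdcd1, 18.4% and 58.3% for Lag3, 63.1% and 15.4% for Tcf7, and 62.1% and 16.6% for Ccr7.

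In CD4 helper T-like cells (1310 and 324 cells, with 5539086 and 1529039 UMIs), Nr4a3 was at 28.5 and 628 CPM, 22.0-fold higher (18.6 to 26.2), and Fosl2 at 45.7 and 622 CPM. Zc3hav1l, Pde4a, Fes, Ell2, Cdkn1a and Kdm2b were between 13.1-fold and 74.5-fold higher. Igfbp4, expressed by naive CD4 T cells, was at 372 and 6.54 CPM, Dapl1 at 259 and 21.6 CPM, and Pik3ip1, an inhibitor of PI3 kinase, at 126 and 7.19 CPM, while Il2ra was at 9.57 and 72.6 CPM. The untreated class lay to 68.5% in a naive-state cluster, cluster 4, and the treated class to 1.23%. Naive CD4 cells may also lie in the CD8 T-like class. Cd4 was found in 15.4% of its mainly treated cluster 5 and in 9.69% of its mainly untreated cluster 2, both with naive-state markers. Without cluster 4 the untreated class was mainly cluster 12 (399 cells), led by Ifit1 and Ifit3. Foxp3 was found in 13.1% and Cd8a in 17.2% of that cluster. The treated class was mainly cluster 19 (283 cells), with Foxp3 in 2.02% and Cd8a in 12.1%. In that comparison Nr4a3 had a log2 ratio of 3.38, Fosl2 2.45, Il2ra 1.57 and Igfbp4 -3.62, whereas Tcf7 changed from -0.44 to 0.33 and Ccr7 from -0.47 to 0.29. With cells named by their own UMIs, Nr4a3 had 3.41 and Tcf7 0.13, while Cdkn1a had 0.85 against 4.34 by clusters, Fes 1.15 against 5.21, Pde4a 2.45 against 5.03, Ell2 2.34 against 4.48, Kdm2b 2.65 against 3.71 and Zc3hav1l 4.84 against 6.22. The chemokine gene Ccl4 had a log2 ratio of -4.56 but 1.25 without doublet removal, and hemoglobin genes reached 721 CPM for Hbb-bs in the untreated class and 0 UMIs in the treated class. Pdcd1, Tox, Foxp3, Ifng, Gzmb and Cd8a had counting intervals that covered 1 or changed direction under other settings, and Cd4, a marker of the class, was 1.62-fold higher.

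The naive list had a median of -0.61 in CD4 helper T-like cells, with 8 of 15 lower, and the ERK list 1.90, with 6 of 7 higher. The ERK median was 1.10 without the naive-state cluster and -0.11 with cells named by their own UMIs, which can lie outside the T-like clusters. Medians of 1.59 for the inhibitory receptor list, 0.88 for activation genes, 0.98 for regulatory T program genes and 0.99 for tissue residency genes came to -0.24, -0.03, -0.42 and -0.38 without the naive-state cluster. Cluster 12, with Foxp3 in 13.1% and Cd8a in 17.2% of its cells, was then most of the untreated class. Cell death and p53 genes stood at 0.87, immediate early genes at 0.64 and ribosomal protein genes at -0.53. Over the 3821 genes with at least 50 UMIs in both libraries the median log2 ratio was 0.37 in this class. That cut is stricter in CPM for the treated library, which had fewer UMIs, so it favours genes higher there. Matched random lists drawn from all measured genes had medians of 0.12 to 0.33. The remaining medians were 0.39 for S phase, 0.37 for chemokine, 0.34 for glycolysis, 0.33 for heat shock and 0.28 for cytotoxic genes. Interferon gamma genes stood at 0.21, type I interferon at 0.10, oxidative phosphorylation at 0.07 and mitochondrial genes at -0.17. These 9 medians, and those of the tissue residency and immediate early lists, lay inside the 95% range of the random lists. After scaling by the median of ratios over those 3821 genes, the naive list stood at -0.98 and the ERK list at 1.53.

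In regulatory T-like cells (782 and 600 cells, with 6330183 and 4602392 UMIs), Il2ra, the high-affinity interleukin-2 receptor chain, was at 196 and 559 CPM, 2.86-fold higher (2.67 to 3.06). Foxp3 was at 255 and 315 CPM; both genes are markers by which the class was named. Effector genes were lower, with Prf1 at 60.0 and 6.52 CPM, Ifng at 48.5 and 7.60 CPM, and Gzmb at 700 and 306 CPM, 2.29-fold lower (2.15 to 2.43), and 6 of 8 cytotoxic genes were at least 1.5-fold lower, with a median of -1.19. The CD8 marker Cd8a was also lower, at 48.5 and 19.3 CPM, a log2 ratio of -1.33 and -0.39 without doublet removal. In that setting Ifng had -1.58 against -2.67 and Prf1 -2.32 against -3.20. The heat shock genes Hspa1a and Hspa1b were 10.0-fold and 6.62-fold lower, Lag3 was 2.22-fold lower and Pdcd1 1.56-fold lower. Zc3hav1l was 18.7-fold, Irs2 8.87-fold, Nr4a3 5.18-fold and the cholesterol exporter gene Abca1 7.54-fold higher, and Cxcl10, an interferon-induced chemokine, was at 42.8 and 206 CPM. Fes, Lars2 and Plagl1 were between 5.74-fold and 9.53-fold higher, and Gzmc, Xcl1, Dapl1 and Igfbp4 between 12.8-fold and 24.2-fold lower. Trdc had 325 UMIs in the untreated class and 0 in the treated class. In cells named by a Foxp3 UMI, Il2ra had a log2 ratio of 1.90, Prf1 -1.98, Cxcl10 0.79, Abca1 1.02 against 2.91 by clusters, Fes 0.02, Gzmc -0.59 and Igfbp4 0.42. Xcl1 had a log2 ratio of -4.60, but -1.38 without doublet removal.

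List medians in regulatory T-like cells were -0.94 for G2M genes, with 13 of 15 lower, and -0.77 for glycolysis genes, with 9 of 14 lower, among them Aldoa at 1079 and 466 CPM and the glucose transporter gene Slc2a1 at 120 and 49.8 CPM. The chemokine list stood at -0.74, type I interferon genes at -0.48, tissue residency genes at -0.33, naive genes at -0.30 and S phase genes at -0.27. The regulatory T program had a median of 0.24, with 4 of 13 higher and 0 lower. Immediate early genes stood at 0.35 and interferon gamma genes at 0.22, activation genes at 0.20, and ribosomal protein genes at -0.16. Inhibitory receptor (-0.12), heat shock (-0.06), oxidative phosphorylation (-0.02), cell death (-0.01) and mitochondrial (0.02) lists lay near 0. These 5 medians and those of the naive, S phase, regulatory T program, interferon gamma, activation and ribosomal protein lists lay inside the 95% range of the random lists. The ERK list had a median of 0.71 over 5 measured genes, with 4 higher. It was -0.21 with cells named by a Foxp3 UMI, which can lie outside the T-like clusters.

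Cells with at least 2 UMIs of G2M genes, after thinning to 2000 UMIs, made up 12.02% of untreated T-like cells (11.3 to 12.8) and 7.71% of treated T-like cells (7.06 to 8.40). The same share was 12.5% and 7.62% in CD8 T-like cells, 25.6% and 15.4% in regulatory T-like cells, and 3.06% and 5.88% in CD4 helper T-like cells. Clusters named as cycling held 6.30% and 2.69% of T-like cells. Without thinning the share was 26.3% and 25.9% in all T-like cells, and 22.2% and 27.6% in CD8 T-like cells, where the order was the opposite. The order in CD8 T-like cells was also the opposite with a minimum of 1 UMI, at 24.97% and 26.9%. Mki67, the proliferation marker, was at 78.4 and 48.2 CPM in CD8 T-like cells, and had a log2 ratio of 1.03 without the cycling clusters.

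Receptor beta V segments were sparsely captured, with 98 Trbv UMIs in untreated and 273 in treated CD8 T-like cells, over 4 segments measured in both libraries. Trbv12-2 took 52.0% (41.7 to 62.2) and 34.8% (29.2 to 40.8), Trbv2 29.6% and 39.9%, Trbv16 11.2% and 21.6%, and Trbv13-2 7.14% and 3.66%. The inverse Simpson index was 2.66 and 3.04. In the other T-like cells, 92 and 34 UMIs were found, with Trbv12-2 at 48.9% and 64.7%. Segments at 0 in a whole library were not measured there, so these shares do not describe the full repertoire.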

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

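Of the tests below, that of the 12 genes in dendritic-like cells and that of how hemoglobin was spread over cells were written before their results were seen, and the other 9 were chosen after.

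The 12 genes with the highest ratios in all T-like cells, among them Nr4a3, Fosl2 and Irs2, were also higher in dendritic-like cells of the treated library. Their median log2 ratio there was 1.77 (1.61 to 1.93), with 11 of 12 higher. Over the 4473 genes with at least 50 UMIs in dendritic-like cells of both libraries the median was 0.14. The 12 genes were higher within T-like clusters with naive-state markers as well (median 3.32, 3.20 to 3.66). This argues against the lower share of naive-state clusters alone as the cause. These cells lay mainly in clusters 1, 2, 4 and 18 in the untreated and cluster 5 in the treated library. Fbxl22, 1 of the 12, was among the top genes of cluster 5. The comparison therefore does not hold the mixture within the naive state constant. Subtracting the T cell share of dendritic-like UMIs (8.53% and 8.47%) left a median of 1.61 (1.43 to 1.80), which argues against free T cell RNA. The dendritic-like mixture differed between the libraries, with cluster 27 holding 88 of 545 untreated and 52 of 136 treated cells. With the 3 clusters of at least 20 cells in each library weighted alike, the median was 1.43 (1.31 to 1.73), which argues against that shift as the whole reason. The median was 3.02 in all T-like cells. Gene by gene the T-like log2 ratio exceeded the dendritic-like one by a median of 1.30 (1.12 to 1.58). With those clusters weighted alike the excess was 1.58 (1.32 to 1.80). For these 12 genes this argues against a difference of the same size in every cell as the whole cause. The genes were picked by their T-like ratio, so a library difference of unlike size by cell type stays open. A difference in handling or library preparation that reached other cell types may explain part of these ratios, since the dendritic-like value of 1.77 lay above the 1.0 set for it. An effect of the drugs on several cell types may do so too and was not tested, and with 1 library per group the batch and the treatment cannot be told apart.

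Hemoglobin transcripts in untreated T-like cells differed 281-fold between the highest class, CD4 helper T-like cells, and the lowest, regulatory T-like cells (187 to 441). This argues against free red cell RNA at a like level in every droplet as the main source. The top 1% of T-like cells held 98.9% of the hemoglobin UMIs (98.7 to 99.1), so red cells or fragments caught in a few droplets may be the source of most of them. Both intervals treat UMIs as independent, so they do not show how far a few droplets could move these values. At least 1 hemoglobin UMI was found in 3.26% of CD8, 1.76% of CD4 helper, 3.20% of regulatory and 2.96% of other T-like cells. A low and even background beside those droplets therefore stays open. No biological explanation was tested.

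In the untreated library, the cells with both T cell and macrophage transcripts (mixed cells) had a median of 17700.5 UMIs. They outnumbered macrophage or monocyte-like cells 25.7-fold (17.5 to 39.3). Macrophage marker UMIs per 10000 were 196.5 in the mixed cells and 112.5 in the macrophage or monocyte-like cells. The naming rule puts a macrophage cluster with enough T cell transcripts in the mixed class, so this excess cannot decide on random pairing. T cell marker UMIs per 10000 of the mixed cells were 4.32-fold those of dendritic-like cells (4.20 to 4.44), at 30.5 against 7.06. They were 1.73-fold those of the 27 macrophage or monocyte-like cells (1.58 to 1.89), at 17.6, so free T cell RNA stays open. Contact between T cells and macrophages that survived dissociation may also explain the 25.7-fold excess, as may macrophages lost from the sort except in pairs, and neither was tested. The treated library held 170 such cells, with a median of 6798.5 UMIs and 76.95 T cell marker UMIs per 10000, against 75.7 in all T-like cells. Each held on average 0.082 times the macrophage marker UMIs of a macrophage or monocyte-like cell (0.064 to 0.106), and 0.0941 times without doublet removal, which argues against random pairs with whole macrophages as their main source. Macrophage RNA in droplets of T cells stays open for them.

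Several list medians had opposite signs in different T cell classes, and none of these differences was tested. S phase genes stood at -0.96 in CD8 and 0.39 in CD4 helper T-like cells, a difference of -1.35, and chemokine genes at -0.98 and 0.37, a difference of -1.35. The chemokine median of CD4 helper T-like cells exceeded that of regulatory T-like cells (-0.74) by 1.11. Cytotoxic genes stood at 0.28 in CD8 and -1.19 in regulatory T-like cells, a difference of 1.46. Glycolysis genes stood at 0.34 in CD4 helper and -0.77 in regulatory T-like cells, a difference of 1.11. Tissue residency genes stood at 0.73 in CD8, 0.99 in CD4 helper and -0.33 in regulatory T-like cells, with differences of 1.06 and 1.32. Several of these signs did not hold under other settings. In CD4 helper T-like cells, median-of-ratios scaling gave 0.02 for S phase, 0.00 for chemokine and -0.03 for glycolysis genes, and tissue residency genes stood at -0.38 without the clusters led by naive or cycling genes. In CD8 T-like cells, cytotoxic genes stood at -0.79 with cells named by their own UMIs, and chemokine genes at 0.56 when genes absent from 1 library were left out of the clustering.

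Of the cells of other types in libraries labelled as T cells, 5 types had higher shares in the treated library, while dendritic-like cells and cells with both T cell and macrophage transcripts had lower shares. B-like cells made up 1.33% of treated and 0.115% of untreated cells, fibroblast-like cells 0.681% and 0.0692%, macrophage or monocyte-like cells 2.59% and 0.311%, natural killer-like cells 1.12% and 0.542%, and neutrophil-like cells 0.981% and 0.173%.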

How the results depend on the processing

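Alternatives that leave out state-led clusters, add back cells kept out, cluster without genes absent from 1 library or compare mean deposited values were chosen after the data were seen; the others were chosen before the data were examined. Of 40 comparisons of 4 class shares, 16 stayed within counting error, 24 moved and 0 reversed. A value was counted as reversed when it was at least 1.5-fold and its sign changed, and for shares when its interval excluded 0, so changes of sign in smaller values were not counted as reversed. The sign was the other one in 1 comparison of shares, 95 of list medians and 102 of named genes. For 75 list medians, 336 of 913 comparisons stayed, 566 moved and 11 reversed in 9 results. For list medians and named genes, differences of mean deposited values are on another scale and could only count as moved or reversed. Where a class held none of the clusters that a setting left out, its values stayed by construction. The counts are therefore no measure of stability. For 238 pairs of a named gene and a T cell class, 1009 of 2400 comparisons stayed, 1375 moved and 16 reversed in 14 results. Values below are treated against untreated, as log2 ratios unless stated, and ERK stands for the median of the ERK pathway output list. The cause was not tested for any of them. In all T-like cells, over the alternatives on the log2 scale, the naive list median lay between -1.48 and -1.16 and Nr4a3 between 3.45 and 3.68.

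Without a cell filter, the share differed (percentage points) by 3.54 for all T, 23.4 for CD8. With 20 components of 3000 genes, the share differed (percentage points) by 6.69 for all T, -9.36 for CD4. With classes from the UMIs of each cell, the share differed (percentage points) by 0.374 for all T, 14.3 for CD8, -4.58 for CD4, -1.78 for Treg. The medians were then 0.81 for ERK in all T, -0.79 for cytotoxic in CD8, 0.69 for inhibitory in CD8, -1.42 for naive in CD8, 1.01 for ERK in CD8. Reversed values were -0.11 for ERK in CD4, -0.21 for ERK in Treg, 0.42 for Igfbp4 in Treg. With at least 500 genes and at most 5% mitochondrial UMIs, the share differed (percentage points) by 28.5 for CD8, -9.63 for CD4, -2.39 for Treg. Values moved to -0.58 for cytotoxic in CD8, 0.55 for inhibitory in CD8, -1.76 for naive in CD8, 1.31 for ERK in CD4. Signs turned to -0.0376 for inhibitory in CD4, 1.30 for Ccl4 in CD4. Without doublet removal, the share differed (percentage points) by 18.9 for CD8, -9.23 for CD4. List medians came to 0.33 for cytotoxic in CD8, 0.83 for inhibitory in CD8, 1.5045 for ERK in CD4. The sign changed to 1.25 for Ccl4 in CD4. At resolution 0.5, the share differed (percentage points) by 28.1 for CD8, -9.39 for CD4. At resolution 2.0, the share differed (percentage points) by 31.3 for CD8, -3.97 for CD4. With the cells kept out added back, the share differed (percentage points) by 16.6 for CD8. List medians came to -0.73 for cytotoxic in CD8, 0.57 for inhibitory in CD8, -1.63 for naive in CD8, 1.44 for ERK in CD8. Without the clusters led by naive or cycling genes, the share differed (percentage points) by 53.3 for CD8, -0.406 for CD4. The medians were then -0.13 for cytotoxic in CD8, 0.20 for inhibitory in CD8, -0.71 for naive in CD8, 1.04 for ERK in CD8, 1.10 for ERK in CD4. Reversed values were -0.0249 for Ccr2 in CD8, -0.16 for Cd274 in CD8, -0.17 for Havcr2 in CD8, -0.36 for Hif1a in CD8, -0.63 for Lag3 in CD8, -0.0405 for Pdcd1 in CD8, -0.24 for inhibitory in CD4, -0.0293 for activation in CD4, -0.42 for Treg program in CD4, -0.38 for tissue residency in CD4, 0.26 for Hba-a1 in CD4. Clustering without genes absent from 1 library, the share differed (percentage points) by 24.2 for CD8, -5.46 for CD4, 0.0396 for Treg. Values moved to 0.21 for cytotoxic in CD8, 1.48 for inhibitory in CD8, -2.03 for naive in CD8, 1.83 for ERK in CD8, 3.84 for ERK in CD4, 0.65 for ERK in Treg. Signs turned to 0.56 for chemokine in CD8. With all T-like cells as denominator, the share differed (percentage points) by -13.3 for CD4. As differences of mean deposited natural log values, the value moved to 0.140 for ERK in all T, 0.173 for cytotoxic in CD8, 0.552 for inhibitory in CD8, -0.541 for naive in CD8, 0.164 for ERK in CD8, 0.0945 for ERK in CD4, 0.263 for ERK in Treg. Reversed values were 0.104 for cytotoxic in all T, 0.0143 for chemokine in all T, 0.142 for Gzmb in all T, 0.0435 for chemokine in CD8, 0.0339 for Cenpa in CD8, 0.341 for Gzmb in CD8. With median-of-ratios scaling, the value moved to 1.18 for ERK in all T, 0.16 for cytotoxic in CD8, 0.83 for inhibitory in CD8, -1.79 for naive in CD8, 1.45 for ERK in CD8, 1.53 for ERK in CD4. With a total without ribosomal, mitochondrial and segment genes, the value moved to 1.10 for ERK in all T, 0.11 for cytotoxic in CD8, 0.71 for inhibitory in CD8, -1.86 for naive in CD8, 1.06 for ERK in CD8, 1.65 for ERK in CD4. With a minimum of 100 CPM, the value moved to 1.61 for ERK in all T, 1.62 for inhibitory in CD8, -1.82 for naive in CD8, 2.21 for ERK in CD8. With no minimum beyond 10 UMIs, the value moved to 0.67 for ERK in all T, 0.89 for inhibitory in CD8, 0.97 for ERK in CD8, 0.57 for ERK in Treg. As the mean of the CPM of each cell, the value moved to 0.78 for cytotoxic in CD8, 1.63 for inhibitory in CD8, 1.97 for ERK in CD8. Without cycling clusters, the value moved to 0.54 for cytotoxic in CD8, 1.61 for inhibitory in CD8, -1.96 for naive in CD8, 1.93 for ERK in CD8. Reversed values were 0.48 for Cenpa in CD8, 1.03 for Mki67 in CD8, 0.24 for Rrm2 in CD8. Without thinning, the cycling share differed (percentage points) by -0.431 for all T, 5.38 for CD8. With a minimum of 1 UMI, the cycling share differed (percentage points) by -0.908 for all T, 1.97 for CD8.

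Depth limits the CD4 helper T-like class most, with 324 treated cells and 1529039 UMIs, and the V segments, with 98 and 273 UMIs in CD8 T-like cells. No paired analysis was possible because each group has 1 library and no result comes from a test.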

Other observations

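Macrophage transcripts in T-like cells went both ways between the libraries, and their source was not tested. Lyz2, a macrophage lysozyme, was at 20.8 and 11.7 CPM in untreated and treated T-like cells, and Apoe, a macrophage lipoprotein gene, at 20.7 and 48.8 CPM. Cluster 23 stayed unnamed and held 168 untreated and 16 treated cells.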
